A study of Mus musculus with 15 samples.

How the data were processed

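Total RNA of mammary gland whole mounts from 15 BALB-neuT mice was labelled with digoxigenin and hybridised to Applied Biosystems AB1700 mouse arrays, a single-colour platform with chemiluminescent detection, per the labels' protocols. Images were acquired and analysed by the manufacturer's protocol, per the labels. Groups were taken from the age in the sample labels, which gave 5 arrays at week 10, 2 at week 15, 4 at week 19 and 4 at week 22. The series design states 1 animal per array. Replicate numbers follow the order of deposit and pair nothing.

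The deposited array files give for each probe a signal intensity on a linear scale with its SD, a signal-to-noise score and a quality flag, per the file headers. In every probe with a signal-to-noise ratio under 1 the deposited signal intensity equals its SD, which held for 31.6% to 39.1% of the probes of an array, so such values mark a floor and not a level. How the background was treated before deposit is not given in the sources used here. The authors' value table holds log2 values that are quantile normalized between arrays. Its columns rank the probes as the scanner signals do (Spearman correlation of 1.0 for all 15 arrays) and have a median of 10.03 each. What offset or floor the authors used is unknown, and the table was used only as an alternative.

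For the main analysis the deposited signals of 33012 probes were taken to log2 and quantile normalized between the 15 arrays, leaving out 303 control spots. A probe was called above background on an array when its signal-to-noise ratio was at least 3 and its flag was under 5000. Probes above background in at least 50% of the arrays of at least 1 age were kept, which left 20867. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) in 1 fit over all arrays with age as 4 levels, and the threshold was a Benjamini-Hochberg adjusted p of 0.05 over all kept probes. A second fit used age in weeks as a number. Arrays of all 4 ages share the estimate of spread, so a group of 2 is assumed to vary like the others.

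Gene names were scarce. The files identify 27930 probes by Celera gene numbers, 4181 by AK numbers of cDNA clones, 517 by RefSeq accessions, 337 by BC numbers and 47 by others. Unversioned accessions and BC symbols were matched to the RefSeq gene table of mouse assembly GRCm38.p6, which named 317 probes of 311 genes and left 32695 probes without a name. The table was used for names only. Of the named probes 211 were kept, for 207 genes, and the probe with the highest mean signal stood for its gene.

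Before the data were examined, 26 gene lists for mammary tissue, tumour, immune and other cell types with 407 genes were fixed. Only 7 of these genes could be named on the array and only the milk protein list, with 4, had the minimum of 3. Basal epithelium, immediate early genes and red blood cells had 1 each, and the other 22 lists, among them adipocyte, luminal, cell cycle, T cell, B cell and macrophage markers, were not analysed here. Another 5 groups were written after the names were known and before the values of their members were examined: lymphoid chemokines and immune receptors, hair and skin, secreted and surface epithelial genes, stromal and adipose genes, and imprinted genes. Lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and with fry. The milk protein p needs no adjustment since 1 planned list was testable, and the 5 added groups were adjusted among themselves. A score per animal, the mean over a list's genes of the log2 signal minus the gene's mean, was tested with a two-sided exact permutation test.

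The rule for the genes named was fixed before the data were examined. For week 22 against week 10 it took the 10 greatest increases and 10 greatest decreases among called genes whose values in the 2 ages do not overlap, of which 10 and 8 existed. For other comparisons it took up to 5 called genes each way, and for each list up to 4 called members or the 2 with the smallest p. Erbb2, Krt18, Adipoq and Mki67 were to be shown always, and no probe could be given these names. Members of the 5 added groups and the genes in the closing observations were named outside this rule, after their values were seen.

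The last part of each label is an array serial number, and the numbers fall in 4 runs, called array series 1 to 4. The file headers give 2 scan days. Both were used as blocks, and values were recomputed within scan days 1 and 2 and within series 3 and 4, which hold arrays of at least 3 ages. Series 2 holds 1 array each of weeks 15 and 22, a pair of ages not compared here. A single array of an age within a batch has no spread of its own, and the ages with several arrays in that batch supply it. For the least gaps given for Krt25, a value below background was set to the 95th percentile of such probes on its array. Scan day 1 held 4 of the 5 week 10 arrays and 1 array of each other age, so it goes with age in part. Within series 4 every week 10 array was of scan day 1 and every later array of scan day 2. Values within series 4 against week 10 therefore also carry any scan day difference. No 2 arrays shared identical values, and the highest correlation between arrays was 0.979. Week 15 replicate 1 stood apart, with a highest correlation to any other array of 0.92, against 0.958 or more for every other array.

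Other alternatives were centring on the 75th percentile or the median, the authors' value table, no filter, a signal-to-noise ratio of at least 3 on every array (11682 probes), an offset of 50, random array series effects, eBayes with trend and robust settings, array weights, fits on only the ages compared, and leaving out each array. The steps were tested on simulated arrays with the means and variances of the 20867 kept probes and 200 changed probes, 3 runs per size. For week 22 against week 10, 75.0% of 4-fold and 16.5% of 2-fold changes were recovered, with means of 10 and 4 false calls per run. For the trend, 87.8% of slopes of 0.2 per week were recovered. Figures were drawn with matplotlib 3.10.9.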

Results

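Mammary gland whole mounts of BALB-neuT mice were profiled at 4 ages. BALB-neuT mice carry an activated rat HER-2/neu oncogene that is expressed in the mammary gland, where carcinomas develop with age, and per the labels the ages stand for progressive stages of that process. All mice were BALB-neuT, so normal ageing of the gland cannot be told apart from that process here. The series held 5 arrays at week 10, 2 at week 15, 4 at week 19 and 4 at week 22, with 1 animal per array per the series design. Each array carried 33012 gene probes read by chemiluminescence. Between 46.1% and 53.9% of the probes had a signal-to-noise ratio of at least 3, and the median signal ranged from 650.2 at week 15 replicate 1 to 1626 at week 22 replicate 4. The number of arrays limits the precision of every value below, most of all at week 15. Levels are log2 signals after normalization, given as mean ± SD, and changes are log2 fold changes ± SE.

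Week 22 was compared with week 10, the latest with the earliest stage. Of the named genes that passed, 3 casein genes had the greatest increases. The casein genes Csn1s2a (NM_007785.1) and Csn2 (NM_009972.1) rose 54.9-fold and 41.5-fold, with log2 changes of 5.78 ± 0.92 and 5.38 ± 0.85 (limma adjusted p = 0.00167 and 0.00154). Csn2 stood at 10.23 ± 0.58 at week 10 (n = 5) and at 15.61 ± 1.55 at week 22 (n = 4). A further casein gene, Csn1s2b, rose 11.7-fold (3.55 ± 0.86, adjusted p = 0.0186) and Wap, which encodes whey acidic protein, rose 3.16-fold (1.66 ± 0.43, adjusted p = 0.0243). With scan day as a block neither of these 2 passed (adjusted p = 0.07 and 0.0692), with array series both did (adjusted p = 0.0276 and 0.0171).

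All 4 measured members of the milk protein list rose, each past the threshold over all kept probes. Their median log2 change was 4.46 (camera p = 5.74e-05, and p = 0.0306 with an estimated correlation). The list score per animal was -1.77 ± 0.50 at week 10 (n = 5) and 2.32 ± 1.01 at week 22 (n = 4), a difference of 4.09 (two-sided exact permutation p = 0.00794, the smallest its splits allow). At week 10, Csn2, Csn1s2b and Wap were each above background on 1 of 5 arrays, so their week 10 levels lie near the floor of the assay and their folds are imprecise. Csn1s2a was above background on 4 of 5, from 9.92 to 12.63. The median change of the list was 3.83 with scan day as a block and 4.73 with array series as a block. Within scan days 1 and 2 it was 3.64 and 4.47, and within array series 3 and 4 it was 6.39 and 3.95.

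Genes of immune cells and lymphoid tissue were higher at week 22 as a group. This group of 11 measured genes was put together after the gene names on the array were known and before their values were examined. It includes near-identical copies such as Ccl21a and Ccl21b, which can share signal. Counts and tests of the group, here and at other ages, treat them as separate genes. Of its members, 4 of 11 rose and none fell, with a median log2 change of 1.12 for the group (camera adjusted p = 2.25e-05 over the 5 groups made this way, and adjusted p = 0.00645 with an estimated correlation). Bcl2a1b, an anti-apoptotic gene of leukocytes with near-identical copies in the mouse genome, rose 3.37-fold (1.75 ± 0.24, adjusted p = 0.000678). Tnfsf13, which encodes the B cell ligand APRIL, rose 2.47-fold (1.31 ± 0.18, adjusted p = 0.000588), and the leukocyte transcript Lst1 rose 2.18-fold (1.12 ± 0.20, adjusted p = 0.00371).

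Ccl21a, a chemokine of lymphoid stroma and lymphatic vessels, rose 5.01-fold (2.33 ± 0.69, adjusted p = 0.0445), a call lost with scan day (2.33, adjusted p = 0.0949) and with array series as a block (2.30, adjusted p = 0.0971), while the fold stayed. Within days 1 and 2 its change was 1.08 and 2.43, and within series 3 and 4 it was 0.35 and 4.06. Its week 22 arrays were spread widely, from 14.10 in replicate 2 to 17.06 in replicate 4. The near-identical Ccl21b changed by 2.10 ± 0.70 (adjusted p = 0.0664) and Ccl19, which acts on the same receptor, by 2.25 ± 0.69 (adjusted p = 0.0508), and neither passed. That Ccl21b value is from the brighter of its 2 probes, and the other one did pass (2.43 ± 0.62, adjusted p = 0.0239). Signal from Ccl21a and Ccl21b cannot be assigned to one copy with certainty. The group's median change was 1.23 with scan day as a block, 1.09 and 1.19 within scan days 1 and 2, 0.99 with array series as a block, and 0.65 and 1.01 within series 3 and 4.

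Among other named genes, Tmem139 rose 4.99-fold (2.32 ± 0.39), Csprs 4.83-fold (2.27 ± 0.34) and Dcaf12l1 3.92-fold (1.97 ± 0.47). Nat8f2, an acetyltransferase family member, was not above background on any week 10 array and rose 3.76-fold (log2 change 1.91, adjusted p = 0.000719). That fold sets the week 22 mean against, per array, the higher of the gene's own value and the lowest value among probes above background. It leaves out the spread between animals, so it is an estimate and not a lower limit.

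Of the named genes that passed, the fall was greatest for Aoc3, an amine oxidase abundant in fat and vessel walls, which fell by 1.46 ± 0.42 on the log2 scale from 19.78 ± 0.49 at week 10 (n = 5) to 18.32 ± 0.80 at week 22 (n = 4; adjusted p = 0.0377). The imprinted genes Ndn, a growth suppressor known from neurons and preadipocytes, and Peg12 fell by 1.42 ± 0.36 and 1.17 ± 0.31 (adjusted p = 0.0223 and 0.0274). Mup1, a major urinary protein whose family members are nearly identical, fell by 1.03 ± 0.20 (adjusted p = 0.00462). Smaller decreases were measured for 2700081O15Rik (-0.90 ± 0.23), Dhrs7b (-0.54 ± 0.15), the dipeptidyl peptidase gene Dpp9 (-0.51 ± 0.14) and Mapk7, which encodes the kinase ERK5 (-0.49 ± 0.13).

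Of the 5 imprinted genes measured, 2 fell and 3 did not pass. Against other genes their group did not pass (median -0.64, camera adjusted p = 0.0951), while its own shift did (fry adjusted p = 0.00699). The group's median was -0.41 with each array centred on its median, and -0.79 and -0.49 with scan day and array series as a block. It was -0.64 and -0.50 within scan days 1 and 2, and -0.32 and -0.58 within series 3 and 4. Their score differed by -0.60 between the ages (exact permutation p = 0.00794, adjusted p = 0.0159 over 6 sets). In the stromal and adipose group of 9 genes, Aoc3 fell, Plin3, a lipid droplet protein, rose 1.45-fold (0.53 ± 0.15, adjusted p = 0.0329), and 7 did not pass (camera adjusted p = 0.877). None of the 4 secreted and surface epithelial genes passed. The other lists with a nameable member had 1 each. Lgals7, known from stratified and basal epithelium, differed by 0.28 ± 0.16 (adjusted p = 0.274), Jun, an immediate early gene, by 0.12 ± 0.32 (adjusted p = 0.84), and the haemoglobin gene Hba-a1 by -0.49 ± 0.30 (adjusted p = 0.32).

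Hair genes set 3 of the 5 week 10 arrays apart. Krt25, a keratin of the hair root sheath, was at 18.74, 17.62 and 15.33 in week 10 replicates 1, 2 and 4, and below background at 8.32 and 8.06 in replicates 3 and 5. At week 22 it was below background on all 4 arrays. None of the 11 hair and skin genes passed the test, with a median log2 change of -2.81 (camera adjusted p = 0.0117, and adjusted p = 0.508 with an estimated correlation). Within scan day 2, which held none of those 3 arrays, the group's median change was 0.23. Without the 3 arrays, an alternative chosen after the data were seen, the median change of the milk proteins was 4.34 and 2225 probes passed, while the call of Mup1 was lost (-0.80, adjusted p = 0.0732).

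**Figure D1:**
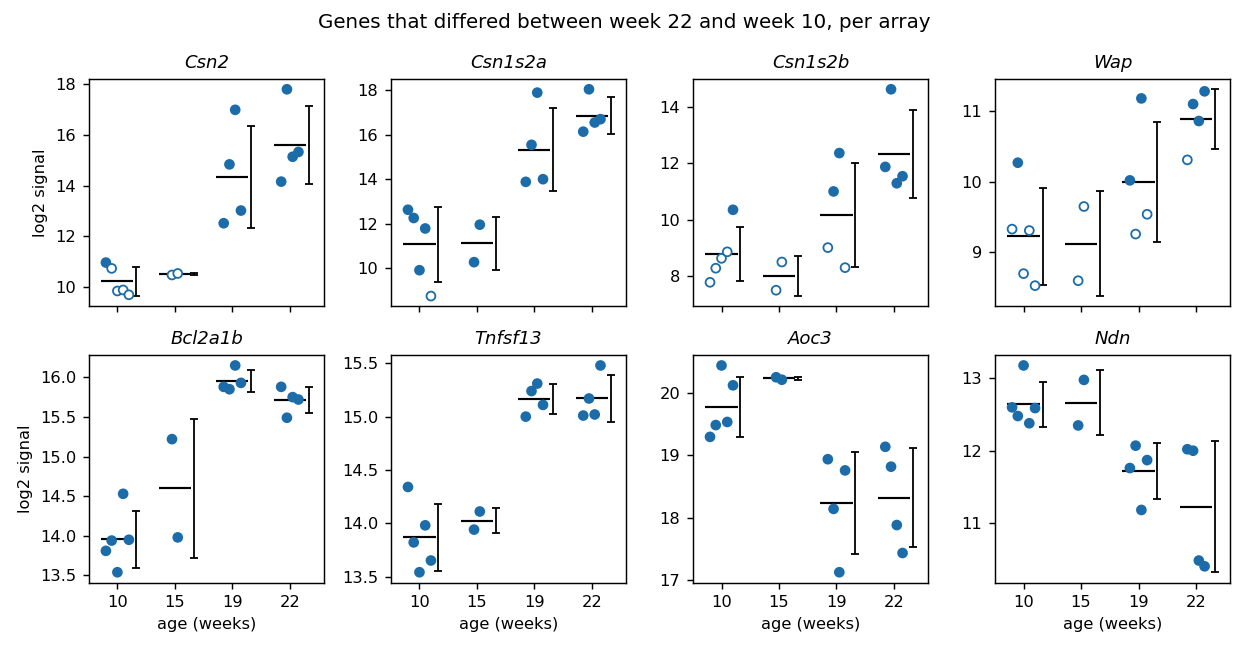
Log2 normalized signal (vertical axes, each with its own range) of 8 genes by age in weeks (horizontal axes). Points are single arrays, filled where the probe was above background and open where it was not, horizontal lines are means and the bars beside them show 1 SD. Csn2 lies between 14.16 and 17.80 on the 4 week 22 arrays and at 10.97 or below on the 5 week 10 arrays, while Aoc3 and Ndn are lower at week 22.

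In total 2495 of 20867 probes passed at week 22 against week 10, 1623 higher and 872 lower, and 1717 of them changed at least 2-fold. Among 207 genes with a name, 19 were higher and 8 lower. Most probes have no gene name here. The most significant of these rose for mCG14724.3 (3.74 ± 0.19, adjusted p = 6.45e-07) and mCG123155.1 (2.54 ± 0.15) and fell for mCG9218.2 (-2.46 ± 0.27) and mCG54122.2 (-1.33 ± 0.16). With each array centred on its median the split was 2674 higher against 500 lower. That scaling placed the median change of all kept probes at 0.14, against -0.01 after quantile normalization, so small decreases depend on it. Dhrs7b, Dpp9, Mapk7, Aoc3 and 2700081O15Rik did not pass under it.

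The count was 1704 with scan day as a block and 2535 with array series as a block. Within scan day 1 (1 array against 4) 4 probes passed, and within scan day 2 (3 against 1) 682 did. Within series 3 (1 against 2) none of the probes passed, and within series 4 (2 against 3) 450 did. In series 4 the week 10 arrays were all of scan day 1 and the week 22 arrays of day 2, so its count also carries scan day. The 18 genes named for this comparison were chosen for values that do not overlap between the 2 ages. That choice fixed their direction within each day and series, but not the size, and Ccl21a changed by only 0.35 within series 3. Of the 18, 9 still passed with scan day as a block and 15 with array series. Lost with scan day were Csn1s2b, Wap, Ccl21a, Aoc3, Ndn, 2700081O15Rik, Dhrs7b, Dpp9 and Mapk7, and with array series Ccl21a, Dhrs7b and Dpp9. Leaving out week 22 replicate 4 or replicate 3 lowered the count to 1211 or 1519. Both are of series 4 and scan day 2 and correlated at 0.979, and no omission removed the pair. Within series 4, whose week 22 arrays are this pair, Ccl21a, Aoc3 and Ndn changed by 4.06, -2.09 and -2.31. Within series 3 (replicate 2) they changed by 0.35, -1.02 and -0.48, and within day 1 (replicate 1) by 1.08, -0.55 and -0.64. Mup1 (-1.11, -0.81 and -1.28) and Csn1s2a (5.01, 7.76 and 4.48, same order) were not greatest with the pair.

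Without week 22 replicate 4, the calls of Ccl21a (1.83, adjusted p = 0.148), Aoc3 (-1.17, adjusted p = 0.13), Wap (1.53, adjusted p = 0.0823) and Ndn (-1.15, adjusted p = 0.0823) were lost. Csn1s2a, Csn2, Csn1s2b, Tmem139, Csprs, Nat8f2, Bcl2a1b and Mup1 passed with each of the 9 arrays left out in turn. The same array ended the calls of Dcaf12l1 (1.89, adjusted p = 0.0584), 2700081O15Rik (-0.77, adjusted p = 0.0917), Dhrs7b (-0.52, adjusted p = 0.0888) and Mapk7 (-0.48, adjusted p = 0.0808). Peg12 was weakest without week 22 replicate 1 (-0.92, adjusted p = 0.0683) and Dpp9 without replicate 2 (-0.44, adjusted p = 0.0903). These 10 genes lost their call for between 2 and 7 of the 9 omissions, Ccl21a and Dpp9 most often.

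At week 19 against week 10 the lymphoid chemokines had the greatest increases of the named genes that passed. Ccl19 rose 31.9-fold (5.00 ± 0.69, adjusted p = 0.000565), Ccl21a 28.5-fold (4.83 ± 0.69, adjusted p = 0.000718) and Ccl21b 25.1-fold (4.65 ± 0.70, adjusted p = 0.000991). Ccl19 stood at 11.30 ± 0.99 at week 10 (n = 5) and at 16.30 ± 0.45 at week 19 (n = 4). In the immune group 8 of 11 genes rose and none fell (median 1.30, camera adjusted p = 8.26e-08, and adjusted p = 0.00132 with an estimated correlation). Its other members that rose included Bcl2a1b (1.99 ± 0.24), Tnfsf13 (1.30 ± 0.18), H2-Q8, a class I gene with close copies (1.45 ± 0.34), and Lst1 (1.12 ± 0.20). The group's median was 1.26 with scan day as a block, 1.09 and 1.52 within days 1 and 2, 1.38 with array series as a block, and 0.97 and 1.63 within series 3 and 4.

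Of the milk proteins, Csn1s2a rose 19.1-fold (4.25 ± 0.92, adjusted p = 0.0098) and Csn2 17.3-fold (4.11 ± 0.85, adjusted p = 0.00738), while Csn1s2b (1.39 ± 0.86) and Wap (0.77 ± 0.43) did not pass. The list's median change was 2.75 (camera p = 0.00435), and the call was lost with an estimated correlation (p = 0.107). It was 2.14 with scan day as a block, 1.39 and 3.36 within days 1 and 2, 3.20 with array series as a block, and 2.31 and 5.21 within series 3 and 4.

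Of the named genes that passed, the greatest falls were those of Pcdha3, a clustered protocadherin (-1.92 ± 0.37, adjusted p = 0.00507), the transcription factor gene Sox11 (-1.70 ± 0.44, adjusted p = 0.0232) and Aoc3 (-1.54 ± 0.42, adjusted p = 0.0288). Sox11 and the olfactory receptor gene Olfr1189 were above background on only 1 of 4 week 19 arrays, so the size of their fall is uncertain. Olfr1189 fell by 1.22 ± 0.36, and the sulfotransferase gene Sult5a1 fell by 1.14 ± 0.29. With scan day as a block Aoc3 (adjusted p = 0.103), Olfr1189 (adjusted p = 0.133) and Sult5a1 (adjusted p = 0.0837) did not pass, and with array series Sox11 (adjusted p = 0.0659) and Olfr1189 (adjusted p = 0.069) did not.

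Ccl19, Ccl21a, Ccl21b, Csn1s2a, Csn2 and Pcdha3 passed at week 19 against week 10 with each of the 9 arrays left out in turn. Olfr1189 lost its call in 7 omissions, Sox11 and Aoc3 in 4 each and Sult5a1 in 2. Sox11 was weakest without week 19 replicate 1 (-1.36, adjusted p = 0.0654), and Aoc3 (-1.17, adjusted p = 0.0986) and Olfr1189 (-1.15, adjusted p = 0.117) without week 19 replicate 3. Sult5a1 did not pass without week 19 replicate 2 (-0.96, adjusted p = 0.0745) or replicate 3 (adjusted p = 0.078).

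At week 19 against week 10, 2612 probes passed, 1519 higher and 1093 lower, among them 17 named genes higher and 10 lower. The count was 1683 with scan day as a block and 2901 with array series as a block. It was 51 within day 1 (1 array against 4), 566 within day 2 (3 against 1), 196 within series 3 (2 against 2) and 103 within series 4 (1 against 3). Without week 19 replicate 3 it was 1415 and without replicate 2 it was 1652. With array weights it was 4240.

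Both comparisons use the same week 10 arrays. Of the probes called in each, 1599 were called in both and all of them in the same direction, 1067 higher and 532 lower, where independent lists of these sizes would share 118.2 and 45.7, a value too low for lists with shared controls. The fold changes correlated across probes at r = 0.830, and groups simulated without any effect against the same controls gave 0.445, with probes not being independent replicates. The covariance was 0.600 against a simulated 0.0717. When the 5 week 10 arrays were split so that each comparison had its own controls, the mean correlation over the 10 splits was 0.638, and a mean of 538 probes was called in both, of 1133.9 and 1773 called. For these counts the smaller part of the controls always went with week 22, so they cannot be compared with each other. Scan day 1 held 4 week 10 arrays and only 1 array each of weeks 19 and 22. A scan day difference can therefore add to the overlap and to the correlation, also with split controls.

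**Figure D2:**
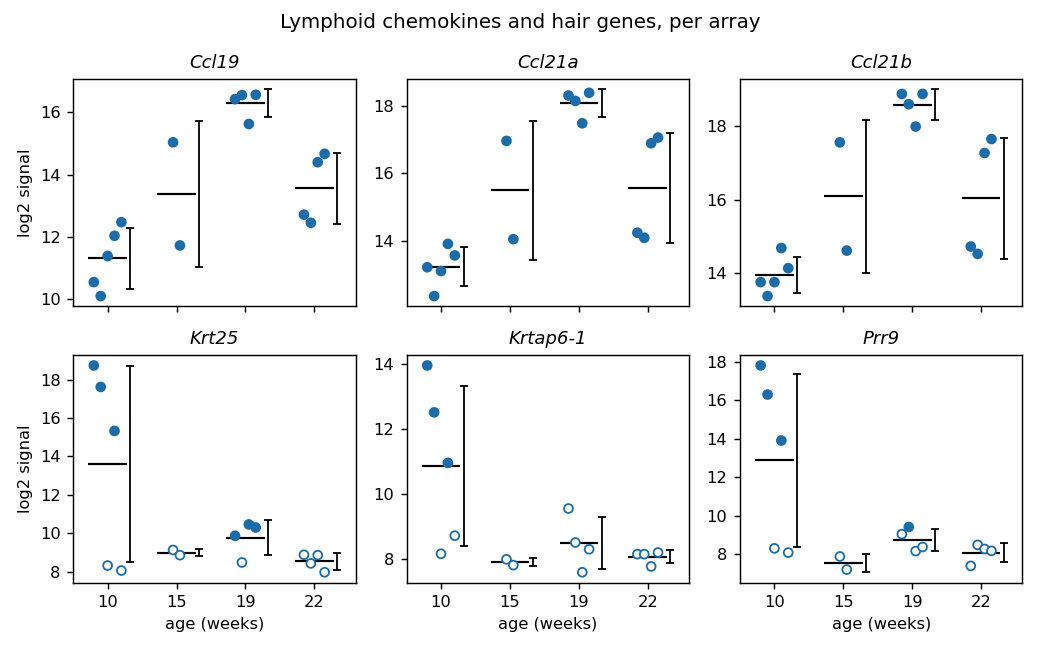
Log2 normalized signal (vertical axes, each with its own range) of 3 lymphoid chemokine genes and 3 hair genes by age in weeks (horizontal axes), with symbols as for the milk proteins. Ccl19 lies between 15.63 and 16.57 on the week 19 arrays, and Krt25 reaches 18.74 on 1 of the 3 week 10 arrays with high hair genes.

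No probe passed at week 22 against week 19 (limma, 0 of 20867, with 1527 at an unadjusted p under 0.05). The difference of Ccl19 was -2.74 ± 0.73 (adjusted p = 0.391) and that of Ccl21a -2.50 ± 0.73 (adjusted p = 0.454). The immune group's median change was -0.24 (camera adjusted p = 0.00868, and adjusted p = 0.0691 with an estimated correlation). Its score per animal was 0.31 ± 0.29 at week 22 and 1.06 ± 0.05 at week 19 (n = 4 each), and the difference of -0.75 had an exact permutation p of 0.0286, the smallest its splits allow, so its adjusted p of 0.172 over the 6 sets could not have been lower for a single shifted set. The scores of the 2 ages do not overlap, and fry called the group (adjusted p = 0.0456). The chemokines Ccl19, Ccl21a and Ccl21b (-2.55 ± 0.73) weighed most in that score. Bcl2a1b, H2-Q7 and H2-Q8 differed by only -0.24, -0.25 and -0.55, and Ifi202b by 0.25, so a fall of the whole group is not shown. Csn2 differed by 1.26 ± 0.89 (adjusted p = 0.825), and the milk protein list by a median of 1.39 (camera p = 0.00387, and p = 0.103 with an estimated correlation).

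The alternatives gave between 0 and 21 probes for this comparison, the most with array weights, and 13 without week 19 replicate 3. It was 1 with scan day as a block and 0 with array series as a block, 8 within day 1 (1 array against 1) and 0 within day 2 (3 against 3), series 3 (1 against 2) and series 4 (2 against 1). Within day 1 all of the spread comes from the week 10 arrays, so those 8 calls are no evidence of a difference between weeks 22 and 19. In simulated data of this comparison, 72.2% of probes changed 4-fold and 13.7% of those changed 2-fold were recovered, so differences of that size can be missed.

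At week 15 against week 10, 7 probes passed, 4 higher and 3 lower, and none of them belongs to a named gene. Csn2 differed by 0.28 ± 1.05 and was not above background on either week 15 array, and Csn1s2a differed by 0.05 ± 1.15. Ccl21a was at 16.96 in week 15 replicate 1 and at 14.06 in replicate 2, and its difference from week 10 of 2.27 ± 0.86 did not pass (adjusted p = 0.375). The hair and skin group had a median change of -2.66 (camera adjusted p = 0.00746, and adjusted p = 0.629 with an estimated correlation), with the 3 week 10 arrays described above as its high values. The milk protein list had a median change of -0.03. Csn2, Csn1s2b and Wap were not above background on either week 15 array, so this value mostly compares floor values and cannot show that nothing changed.

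The week 15 count depends on single arrays. It was 943 without week 15 replicate 2, when replicate 1, assumed to vary like the other ages, stands alone, 11 without week 15 replicate 1, and 47, 3, 4 and 11 without week 10 replicates 3, 1, 2 and 4. It was 9 with scan day as a block and 1 with array series as a block, 327 within day 1 (1 array against 4) and 0 within day 2 (1 against 1) and series 4 (1 against 3). Simulated 2-fold changes were recovered in 0.167% of probes and 4-fold changes in 65.3%, which bounds what 2 arrays can show.

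Week 19 against week 15, the step between the middle ages, showed 2 of 3 casein genes and 5 of 11 immune genes higher, while Csn1s2b (2.17 ± 1.11, adjusted p = 0.197) did not pass. Csn1s2a rose 18.4-fold (4.20 ± 1.19, adjusted p = 0.0366), and Csn2, below background at week 15, rose 14.3-fold (3.83 ± 1.09, adjusted p = 0.0373). Ccl19 rose 7.54-fold (2.92 ± 0.90, adjusted p = 0.0477), the keratin gene Krt23 4.94-fold (2.30 ± 0.58, adjusted p = 0.025) and H2-Q8 4.61-fold (2.20 ± 0.43, adjusted p = 0.0104). Of these 5, Csn1s2a (adjusted p = 0.0537 and 0.0817), Csn2 (adjusted p = 0.0525 and 0.0914) and Ccl19 (adjusted p = 0.0663 and 0.17) passed with neither scan day nor array series as a block, Krt23 only with scan day (adjusted p = 0.0387), and H2-Q8 with each. In the immune group none fell (median 1.27, camera adjusted p = 6.77e-06, and adjusted p = 0.00441 with an estimated correlation). Its median was 1.32 and 1.62 with scan day and array series as a block, 1.14 and 1.16 within days 1 and 2, and 1.86 within series 4.

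The membrane receptor gene Paqr9 fell by 2.49 ± 0.58 (adjusted p = 0.0191), Sox11, above background on only 1 of 4 week 19 arrays and so of uncertain size, by 2.50 ± 0.57 (adjusted p = 0.0178), Pcdha3 by 2.02 ± 0.47 (adjusted p = 0.0196), Aoc3 by 2.00 ± 0.54 (adjusted p = 0.0313) and Sowahc by 1.44 ± 0.41 (adjusted p = 0.0381). With scan day as a block all but Sowahc passed (adjusted p = 0.054), and with array series only Paqr9 did (adjusted p = 0.0471).

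Each of these 10 genes lost its call at week 19 against week 15 without one of the 2 week 15 arrays. Ccl19 changed by 1.25 (adjusted p = 0.381) without replicate 2 and by 4.58 (adjusted p = 0.0272) without replicate 1. H2-Q8 changed by 1.32 (adjusted p = 0.119) without replicate 1 and by 3.09 without replicate 2, and Krt23 by 1.96 (adjusted p = 0.18) and 2.65. Without replicate 1 the other calls were lost as well, for Csn1s2a (3.36, adjusted p = 0.253), Csn2 (3.80, adjusted p = 0.175), Sox11 (-2.59, adjusted p = 0.0939), Paqr9 (-2.56, adjusted p = 0.102), Pcdha3 (-2.36, adjusted p = 0.0672), Aoc3 (-1.98, adjusted p = 0.158) and Sowahc (-1.59, adjusted p = 0.138). These 7 did not pass without replicate 2 either. Leaving out any 1 of the week 19 arrays also ended the call of Ccl19 (adjusted p = 0.0725 to 0.0891). Without week 19 replicate 2 or 3, Csn1s2a, Csn2, Krt23, Aoc3 and Sowahc did not pass, nor did Sowahc without replicate 1. H2-Q8, Sox11, Paqr9 and Pcdha3 passed with each week 19 array left out. Of the milk protein list, 2 of 4 rose and 2 did not pass (mean 2.77, camera p = 0.00993), and the call was lost with an estimated correlation (p = 0.14).

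In all, 2832 probes passed at week 19 against week 15, 1389 higher and 1443 lower, and 1142 higher against 1839 lower with each array centred on its 75th percentile. Without week 15 replicate 1 the count was 521, without week 19 replicate 3 it was 988 and without week 19 replicate 2 it was 1305. It was 2187 with scan day as a block, 900 with array series as a block, 42 within day 1 (1 array against 1), 703 within day 2 (3 against 1) and 0 within series 4 (1 against 1). A single array has no spread of its own, which within day 1 and series 4 is borrowed wholly from other ages and within day 2 comes from weeks 19 and 22, so these counts are weak evidence.

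A linear trend over age in weeks was called for 3326 probes, 1981 rising and 1345 falling, with 25 rising and 13 falling among the named genes. Csn1s2a rose by 0.50 per week on the log2 scale (adjusted p = 0.00108), Csn2 by 0.46 (adjusted p = 0.000857) and Bcl2a1b by 0.17 (adjusted p = 0.000553). The casein slopes need not mean a steady rise, since at week 15 against week 10 Csn1s2a differed by 0.05 ± 1.15 and Csn2 by 0.28 ± 1.05. Aoc3 fell by 0.14 per week (adjusted p = 0.0212) and Mup1 fell by 0.09 (adjusted p = 0.00519). The split was 2658 rising against 768 falling with each array centred on its median. The count was 1782 with scan day as a block and 4359 with array series as a block, 0 within day 1 (7 arrays), 763 within day 2 (8 arrays), 0 within series 3 (5 arrays) and 1000 within series 4 (7 arrays), and it was 2131 without week 22 replicate 4. In series 4 week 10 and the later ages also differ in scan day.

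**Figure D3:**
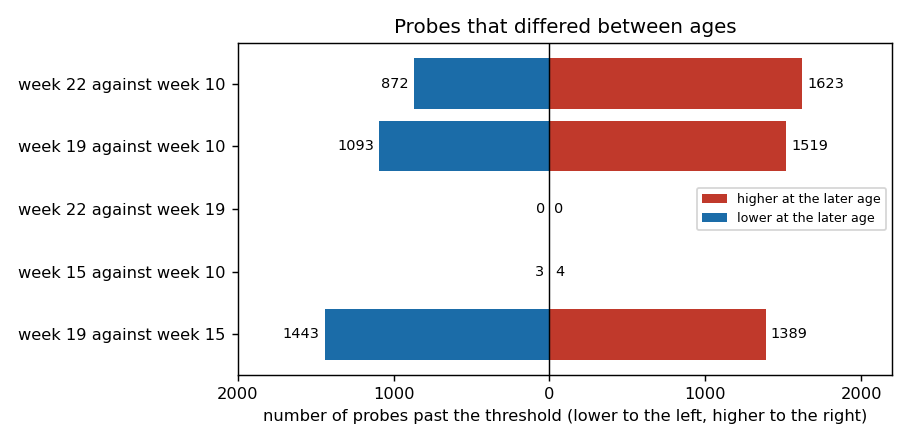
Number of probes past an adjusted p of 0.05 in each comparison of 2 ages (rows), with those higher at the later age drawn to the right and those lower at the later age to the left of 0 (horizontal axis, probes). The bars reach 1623 and 872 for week 22 against week 10, and week 22 against week 19 has 0 on both sides.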

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

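Of 111 sets of values tested, each a gene or group score within 1 age with 4 or 5 arrays, 5 held an array far from the others of its age by Dixon's criterion, and chance alone marks about 1 in 20. Ndn was at 13.18 in week 10 replicate 3, above the range of 12.38 to 12.60 of the other week 10 arrays. Jun was at 15.31 in the same array, below the range of 16.20 to 16.52. Sox11 was at 9.03 in week 10 replicate 1, where it was not above background, against 10.43 to 10.95 in the others. Ccl19 was at 15.63 in week 19 replicate 3, against 16.43 to 16.57. The score of the imprinted genes was -0.06 in week 19 replicate 2, against -0.32 to -0.28 in the other week 19 arrays.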

How the results depend on the processing

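The scan day block, the fits without the 3 week 10 arrays with high hair genes and the Ccl19 and Ccl21a covariate were chosen after seeing the data. The adipocyte covariate was not run, since no member of that list has a name here. The shift of the milk proteins passed in all 19 alternatives (median 3.72 to 4.78, p up to 0.0306), and so did their score in all 12 (3.602 to 4.36, exact permutation p up to 0.0286). The cause was not tested for the values below, except that left-out arrays and fits on 2 ages hold fewer samples and the covariate follows age.

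At week 22 against week 10, array weights gave 5158 probes, the covariate 474, and single left-out arrays 1211 to 2475. At least 2-fold changes as well left 1717. At week 19 against week 10, array weights gave 4240, the scan day block 1683, the covariate 1, and left-out arrays 1415 to 2752. At week 19 against week 15, no filter gave 1522, the array series block 900, array weights 1118, fits on the 2 ages 1799, and left-out arrays 521 to 2521. At week 15 against week 10, 75th percentile centring gave 2, signal-to-noise of at least 3 on every array 0, the array series block 1, the random array series effect 11, trend and robust settings 0, array weights 3, the 2 ages alone 0, the fit without the 3 week 10 arrays 0, and left-out arrays 3 to 943. At week 22 against week 19, median centring gave 3, the stricter signal-to-noise filter 1, the offset 1, trend and robust settings 1, array weights 21, the 2 ages alone 1, the scan day block 1, and left-out arrays 0 to 13. For the trend, array weights gave 5406, the scan day block 1782, and left-out arrays 2131 to 3810.

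The 31 named genes had 702 alternative values at week 22 against week 10, of which 572 kept direction and side of the threshold, 95 lost and 28 gained a call, and 7 changed sign. Jun changed sign with the array series block (-0.014), array weights (-0.29) and left-out arrays (-0.19 to 0.32), and Ccl19 (-0.039), Ccl21b (-0.17) and Pcdha3 (0.15) with the covariate, none of them called. Ccl19 is part of that covariate and Ccl21b nearly a copy of its other part, so their change is removed by construction. About 50% of the probes lie near background, which limits folds of dim genes such as Wap.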

Other observations

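Genes named here were picked after their values were seen. At week 22 against week 10, Chrnb1, a subunit of the muscle acetylcholine receptor, was higher by 1.59, Tceal9 by 1.40 and the tyrosine kinase gene Tnk1 by 1.23 on the log2 scale (limma adjusted p = 0.00257, 0.00389 and 0.0426). At week 19 against week 10 the transcription factor gene Cebpb was higher by 0.72 on its brighter probe (adjusted p = 0.0249) and not called on its other one (0.59, adjusted p = 0.463), and the interferon-induced family member Trim34a was higher by 0.90 (adjusted p = 0.0243). The receptor accessory gene Ramp3 was higher by 1.94 at week 19 against week 15 (adjusted p = 0.018). Pemt, an enzyme of phosphatidylcholine synthesis, was lower there, at -0.83 (adjusted p = 0.0493).

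Chosen only after results were seen were the fold ratio with the chemokine covariate, the 22 probes that followed Ccl21a, the tests of the chemokines against scan day and gene copies, both tests on hair genes, the step test and the other splits for week 22 against week 19. The covariate was also added after the data were seen. Chance is an unlikely source of 3 counts. Only the real grouping, 1 of 100 splits of the same arrays, gave as many calls for week 22 against week 10 (2495, highest other 450) and for week 19 against week 10 (2612, highest other 1209), and 1 of 100 orders of the ages did for the trend (3326, highest other 2). For week 22 against week 19 the real count was 0, which every split reaches, so its 35 of 35 splits (highest other 27) carry no information.

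The difference between week 22 and week 10 was weighed against batches and tissue makeup. Of the probes called within scan day 2, 94.3% had the same direction within scan day 1, on other animals, so scan day alone is not a sufficient source. The fold changes within series 3 and series 4 correlated at 0.492 across probes, so array series alone is not either. Within series 4 the week 10 arrays were all of day 1 and the week 22 arrays of day 2, so that correlation can also hold a scan day difference. For tissue that carries Ccl19 and Ccl21, the prediction written beforehand was that under 25% of the called probes would still pass with the mean of Ccl19 and Ccl21a as a covariate, and 18.2% did, so that prediction was met. A ratio of adjusted to plain folds, chosen after this was seen, had a median of 0.922, with median absolute folds of 1.30 before and 1.15 after and median SEs of 0.287 and 0.386. Age accounts for 0.801 of the variance of this covariate, so the 2 tests cannot separate such tissue from age. It stays open beside other changes in tissue makeup and changes within cells.

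Ccl19, Ccl21a and Ccl21b differed between arrays of 1 age, more so at weeks 15 and 22 than at weeks 10 and 19. Their SDs were 1.14 to 1.65 at week 22 and 0.41 to 0.45 at week 19. At week 10 they were 0.58 and 0.49 for Ccl21a and Ccl21b, but 0.99 for Ccl19, close to its 1.14 at week 22. Scan day is not the source, since Ccl21a spans 2.96 log2 units over the 3 week 22 arrays of day 2. Ccl19, a separate gene, spans 2.22 over the week 22 arrays, so the spread is not confined to the Ccl21 copies. That value cannot tell how much signal those copies share. The test set beforehand counted against an RNA source shared between samples, since the 824 probes 4-fold higher in week 15 replicate 1 than in replicate 2 had a median within-age correlation of -0.04 with Ccl21a. Replicate 1 is also the dimmest array, and whether that affected the result was not tested. A test added after that result pointed the other way, as 22 probes that followed Ccl21a within weeks 10, 19 and 22 were higher in replicate 1 by a median of 1.85 (quartiles 0.933 and 2.67). The question is left open, and lymph node tissue in the whole mounts may be one source and lymphatic or immune stroma that changes with age another.

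All 8 hair genes (Krt25, Krt27, Krtap1-5, Krtap4-2, Krtap4-7, Krtap6-1, Krtap9-3 and Prr9) had week 10 replicates 1, 2 and 4 as their 3 highest arrays, but these 8 were picked after their values were seen, so the count only restates the pattern. In the whole group it held for 9 of 11 genes, not for Edar or Lgals7. Scan day and array series are not the source, since Krt25 in week 10 replicate 3, of the same day and series as replicates 1 and 2, lies at least 8.37 log2 units below the highest array, and 4 of 7 arrays of scan day 1 and 5 of 7 of series 4 lie at least 4.52 and 4.87 below the lowest of the 3. A candidate source is skin with growing hair follicles taken with the gland, and a hair cycle stage that depends on age stays open as the biological alternative.

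A last hypothesis, formed after the counts were seen, was that the change came in a step between weeks 15 and 19. Over the probes called at week 22 against week 10, the median ratio of the week 15 change to the week 22 change was 0.0726, against 0.417 for a steady change over 5 of 12 weeks, and 0.0746 and 0.0547 for each week 15 array alone. The median ratio of the week 22 against week 19 change was 0.139. With 2 arrays at week 15 the timing may still shift with more animals.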
